A study of Macaca mulatta with 15 samples.

How the data were processed

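RNA was measured in 15 libraries of peripheral blood T cells from 2 healthy rhesus macaques, named RhDBCb and RhM22 in the labels. Each library holds 1 of 4 subsets, CD4 naive, CD4 memory, CD8 naive or CD8 memory, drawn before or after treatment with 2-hydroxypropyl-beta-cyclodextrin, a ring of sugar units that binds cholesterol. Per the labels, polyadenylated RNA was purified with the RNeasy Micro kit and made into libraries with SMART-Seq v4, which does not mark strand. How the subsets were separated is not stated in the labels. The CD8 naive cells of RhDBCb after treatment were not analysed here.

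Both units were deposited by the authors with 1 column per library. The first is the expected count per gene, which the authors estimated with RSEM from aligned reads and deposited without scaling. Per the submitters' processing notes the tools were cutadapt 1.18, STAR 2.7.6a and RSEM 1.3.3, and the genome builds Mmul_10 and rheMac10. The second deposited unit is FPKM, for which the authors divided the counts by gene length and by a scale factor per library that differs from the library's total count. Neither the origin of that scale factor nor any filter is stated. The counts cover 34884 genes and the FPKM values 28331 of them. The other 6553 genes had 0 counts in every library.

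The expected counts were rounded to whole numbers, which moved a library total by at most 26.1 counts. Gene symbols came from the deposited table for 23407 genes and from a table of gene names for a further 933. That table held 24022 of the gene IDs. The 10544 genes left without a symbol took 3.4% to 8.3% of the counts. No genome sequence was used, so no positions are given. Total counts ranged from 44414963 to 71787211 per library. PCR copies cannot be told from separate molecules in these libraries, so a count's own error is larger than depth alone implies.

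Genes were filtered with edgeR's filterByExpr by subset and time with a minimum count of 10, which kept 14814 genes. Counts were scaled with TMM factors, and CPM values were computed from the scaled totals. Differences were tested with edgeR's quasi-likelihood F test, and p was adjusted by the Benjamini-Hochberg method over all genes tested. The SE of a log2 fold change was derived from this test, as its absolute value divided by the square root of F. A gene was called at an adjusted p under 0.05. All 15 libraries shared 1 estimate of the spread, because a subset and time had only 1 or 2 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

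The effect of treatment over all subsets was the after-minus-before term of a model with subset and animal. Effects in single subsets, the differences between these effects and the contrasts between subsets before treatment came from a model of 8 subset-by-time groups plus animal. Whether the animals changed differently was the animal-by-time term, RhM22 minus RhDBCb, of a model with subset. These comparisons, 35 gene lists and the rule for the genes named were fixed before the data were examined. The change within each animal, the animals compared at each time and the fit without the before libraries of RhDBCb were added after the data were seen.

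The gene lists were tested with limma's camera on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Each list's members were also counted with p adjusted over all genes and adjusted over the list alone. A list's median is the median log2 fold change of its measured members.

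For treatment over all subsets the rule named up to 10 genes in each direction with the largest fold change among those called. They had to have a symbol, a mean CPM of at least 5 and the same direction in both animals. The rule took 5 per direction for each subset and 6 for each contrast between subsets. Where none passed, it took the 5 genes with the smallest p as values. It also took up to 2 members per direction of each list, and a fixed panel of genes of sterol metabolism, interferon response, proliferation, activation and T cell identity. Genes named for a single animal, and for the difference between the animals, were the 10 per direction by the same rule, and a few list members beside them were chosen after their values were seen. So were the list members named in the contrasts between subsets, and BCL6, SPECC1L, IFIT3 and NABP1 under treatment over all subsets. A few genes that the rule or the panel took are not reported here, and all fits, counts and list tests keep them.

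Samples are paired because libraries of the same animal carry its name in the labels. Deviations from the group means correlated between libraries of the same animal at 0.154 to 0.442 across the 7 groups with both animals. Before and after libraries of a subset correlated at 0.276 in CD4 naive, 0.378 in CD4 memory and 0.26 in CD8 memory. These correlations are across genes, which are not independent replicates. Among 105 pairs of libraries no duplicate was found, since the smallest mean chi-square per gene was 74.5 where sampling noise alone gives 1.

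The procedure was tested on simulated data, with counts drawn for the 14814 genes and 200 of them changed by 2-fold or 4-fold in equal numbers. For treatment over all subsets 65% of the 2-fold and 98% of the 4-fold changes were recovered. In single subsets 4% to 13% of the 2-fold and 46% to 73% of the 4-fold changes were recovered. In RhDBCb the shares were 31% and 83%, and in RhM22 52% and 92%. False calls were 8 of 171 calls over all subsets, 6 of 120 in RhDBCb and 20 of 164 in RhM22. In CD4 naive, CD4 memory, CD8 naive and CD8 memory cells they were 2 of 78, 9 of 91, 2 of 52 and 7 of 91. Data simulated without any difference between the animals gave 1 false call for the animal-by-time term. The libraries were simulated independently, with no effect shared by libraries of the same animal and time. These false calls therefore give no measure of chance among draws.

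The alternatives tried were RLE size factors in edgeR, the DESeq2 Wald test, limma voom with the draw as a random block, no animal block, a block by animal and subset, and a fold threshold of 2. Further ones were no low-count filter, with at least 1 count in any library, and a filter of CPM 5 in 4 libraries. The deposited FPKM values were tested with limma trend as log2 with 1 or 0.1 added, filtered and unfiltered. Samples were varied by fitting each animal alone, only the groups compared, all libraries but the CD8 naive ones, and by leaving out each library in turn.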

Results

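The series holds 15 RNA-seq libraries of T cells from the blood of 2 healthy rhesus macaques, RhDBCb and RhM22, drawn before and after daily subcutaneous 2-hydroxypropyl-beta-cyclodextrin. The dose was 1 ml/kg/day of a 15% (w/w) solution, given for up to 120 days per the labels. Of the 8 subset-by-time groups 7 hold 2 libraries, 1 per animal, and CD8 naive cells after treatment are represented by RhM22 alone. The libraries come from 4 draws, 1 per animal and time, and make 7 before-and-after pairs. Their totals ranged from 44414963 to 71787211 counts, with 13525 to 15445 genes detected and 8.2% to 15.1% of the counts in the top 10 genes.

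Lineage markers followed the labels. CD4, the co-receptor of helper T cells, lay at 207 to 549 CPM in the 8 CD4 libraries and at most 1.68 CPM in the 7 CD8 libraries. CD8A, a chain of the co-receptor of cytotoxic T cells, lay at 665 to 861 CPM in the CD8 libraries and at most 3.93 CPM in the CD4 libraries. The Y-linked ribosomal gene RPS4Y1 lay at 200 to 273 CPM in the 7 libraries of RhDBCb and at most 0.457 CPM in the 8 of RhM22. The first principal component, with 23.0% of the variance, put all libraries of RhDBCb (-128 to -11.1) below all of RhM22 (16.2 to 98.4). The before libraries of RhDBCb held 13525 to 14750 detected genes, and its CD4 naive, CD4 memory and CD8 naive ones held the fewest of the series.

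The first comparison asked what changed in T cells over the course of treatment, across all subsets and both animals. IFIT2 (ENSMMUG00000061761), an interferon-induced gene of antiviral defence, fell by 1.36 on the log2 scale (SE 0.18, edgeR adjusted p = 0.0292) and was lower after treatment in 7 of 7 pairs. In RhDBCb its mean went from 71.3 ± 26.0 CPM (SD over subsets, n = 4) to 36.3 ± 11.7 (n = 3), and in RhM22 from 98.7 ± 63.1 (n = 4) to 37.5 ± 22.9 (n = 4). It was the 1 gene called of 14814 tested, with 1526 genes at an unadjusted p under 0.05. The next in order of p did not pass. BCL6, the repressor that directs follicular helper cells, had a log2 fold change of -1.13 (SE 0.17, adjusted p = 0.0541), and SPECC1L, a cytoskeletal gene, 0.73 (SE 0.11, adjusted p = 0.0541). IFIT3, a relative of IFIT2, lay at -1.03 (SE 0.19, adjusted p = 0.114) and NABP1, of DNA repair, at -0.86 (SE 0.16, adjusted p = 0.114).

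Only 4 of the 15 fits that left out 1 library kept the IFIT2 call. These left out the CD4 naive before library of RhDBCb (adjusted p = 0.0492) or of RhM22 (0.0306), the CD8 memory before library of RhDBCb (0.000276) or the CD8 memory after library of RhM22 (0.0311). Each of the other 11 libraries was needed for the call, with adjusted p up to 0.153 without one, though the fold change stayed between -1.49 and -1.26. The count was 2 without the CD4 naive or the CD8 memory before library of RhDBCb, 3 without the CD8 memory after library of RhM22 and 0 without each of those 11. DESeq2 called 177 genes, IFIT2 among them, and edgeR without the animal block called 0, with IFIT2 at adjusted p = 0.109. In edgeR with the animal-by-time term in the model, the change averaged over the animals was called in 200 genes. With the 4 before libraries of RhDBCb left out, a fit chosen after the data were seen, 11 genes were lower, with IFIT2 at 0.00379. RhDBCb then has no before-and-after pair, so that fit gives the change in RhM22 and not one over both animals.

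Cyclodextrin binds cholesterol, so genes of sterol balance were followed as a fixed set. None of those reported here passed the test over both animals. SQLE, an enzyme of cholesterol synthesis, had a log2 fold change of -0.16 (SE 0.14, adjusted p = 0.712), and HMGCS1, an earlier one, 0.04 (SE 0.26, 0.976). INSIG1, the sterol-regulated brake on the pathway, lay at -0.09 (SE 0.12, 0.843). The efflux transporters ABCA1 and ABCG1 lay at 0.15 (SE 0.35, 0.918) and -0.24 (SE 0.12, 0.523), and MYLIP, a ubiquitin ligase induced by sterols, at -0.22 (SE 0.18, 0.708). SREBF1, the transcription factor of lipid synthesis, had a value of 0.65 (SE 0.36, 0.553), and differed between the animals. Of 28 measured targets of cholesterol synthesis and uptake 14 lay above 0 (median -0.01, camera adjusted p = 0.876). The 14 genes of sterol efflux had a median of 0.01 and a mean of 0.24 (0.978), where camera's direction was down, and the 26 lysosomal genes 0.09 (0.334).

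**Figure D1:**
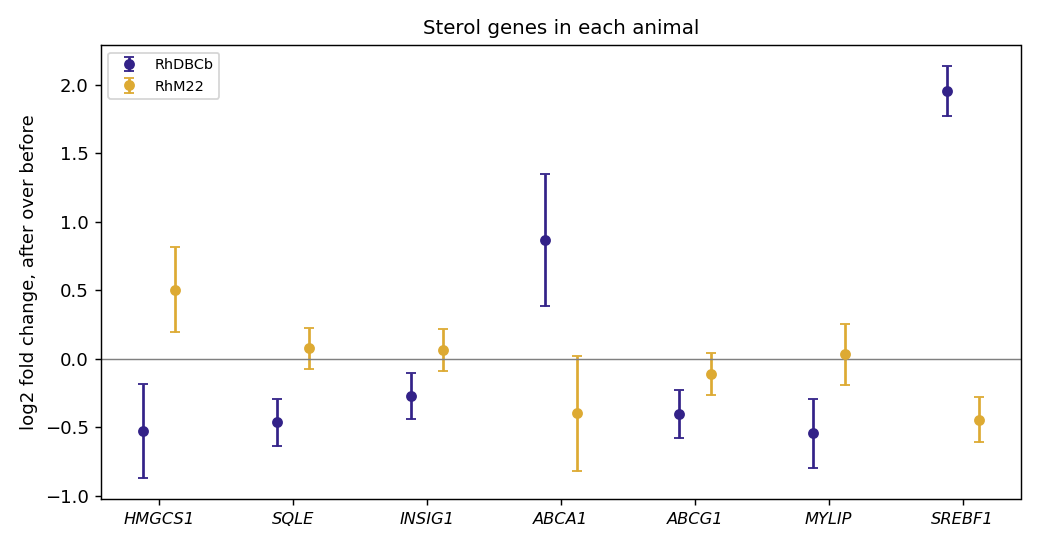
Log2 fold change (after against before, ± SE) of 7 genes of sterol synthesis, its regulation and efflux in RhDBCb and RhM22. SREBF1 lay at 1.95 in RhDBCb and at -0.44 in RhM22, while SQLE over both animals lay at -0.16.

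The fixed panel of interferon, activation, proliferation and identity genes held no further call over both animals. MX1, an interferon-induced antiviral GTPase, lay at 0.83 (SE 0.43, adjusted p = 0.526), ISG15, a ubiquitin-like interferon product, at -0.25 (SE 0.18, 0.67), and IFI6 at 0.30 (SE 0.15, 0.492). The activation markers CD69, IL2RA and CD38 lay at -0.55 (SE 0.28, 0.516), -0.64 (SE 0.40, 0.595) and 0.18 (SE 0.14, 0.685). MKI67 and TOP2A of dividing cells lay at -0.37 (SE 0.49, 0.836) and 0.08 (SE 0.32, 0.951). The cytotoxic genes GZMB and PRF1 lay at -0.51 (SE 0.33, 0.625) and 0.09 (SE 0.28, 0.942). Among early response genes JUN lay at -0.76 (SE 0.40, 0.525), FOS at -0.40 (SE 0.29, 0.655), NR4A1 at 0.35 (SE 0.16, 0.467) and TNFAIP3 at -0.57 (SE 0.22, 0.425). The homing receptor CCR7 lay at -0.32 (SE 0.20, 0.587). CD8A and CD8B lay at 0.08 (SE 0.19, 0.923) and -0.28 (SE 0.17, 0.589), and CD4 at 0.00 (adjusted p = 1).

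Camera with its preset correlation called 6 of the 35 gene lists over both animals. Interferon-gamma and antigen presentation genes had a median log2 fold change of -0.33 with 4 of 19 members above 0 (adjusted p = 0.000617), TNF and NF-kB signalling genes -0.22 (0.00299), nuclear genes of oxidative phosphorylation -0.11 (0.00139) and proliferation genes -0.13 (0.0113). The 13 mitochondrially encoded genes had a median of 0.19 (0.00541). Their pair medians ran from -0.61 in CD8 memory to 1.25 in CD4 naive cells, both of RhM22. Those of proliferation genes ran from -1.76 in CD8 memory to 0.64 in CD4 naive cells, both of RhDBCb. Platelet markers lay above 0 in 11 of 11 members with a median of 1.23 (5.43e-05). None of the 6 held with an estimated correlation. The adjusted p was then 0.267 for interferon-gamma genes, 0.484 for NF-kB, 0.854 for oxidative phosphorylation, 0.906 for proliferation, 0.854 for mitochondrially encoded genes and 0.484 for platelet markers. IFIT2 was the only member of any list called over all genes. Adjusted over the list alone, 2 platelet markers were higher, and 2 type I interferon-stimulated genes and 1 NF-kB gene were lower.

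Type I interferon-stimulated genes as a list had a median of 0.00 over both animals, with 23 of 47 members above 0 (camera adjusted p = 0.417). T cell activation markers lay at -0.14 (0.682), immediate early genes at -0.10 (0.334), cytokines and their receptors at -0.07 (0.743), and cytotoxic genes at -0.08 (0.856), where camera's direction was up. Naive T cell genes lay at 0.06 (0.682), memory markers at -0.15 (0.588), inhibitory receptors at -0.01 (0.876), T helper genes at -0.11 (0.334) and homing receptors at -0.04 (0.856). Adjusted over the list alone, naive genes had 1 member higher and 1 lower, T helper genes 2 lower, homing receptors 2 higher and 3 lower, and glycolysis 1 lower. Stress lists stayed within the test too: heat shock 0.03 (0.856), the unfolded protein response -0.12 (0.106), p53 and apoptosis 0.01 (0.647). Glycolysis lay at -0.08 (0.1), ribosomal proteins at 0.01 (0.876), T cell receptor signalling at 0.08 (0.381), the TGF-beta response at 0.03 (0.876) and the glucocorticoid response at 0.08 (0.856). Markers of other cells were likewise not called: B cells 0.28 (0.1), monocytes and dendritic cells 0.33 (0.257), neutrophils -0.09 (0.876), natural killer cells -0.11 (0.913), erythroid cells 0.36 (0.417), and gamma-delta T cells -0.27 (0.962). CD4 and CD8 lineage lists lay at -0.15 (0.955) and 0.00 (0.876). Camera's direction differed in sign from the median for inhibitory receptors, p53, TGF-beta, glucocorticoid, neutrophil, natural killer, gamma-delta and CD8 lineage genes. For type I interferon-stimulated genes and the glucocorticoid response the mean, 0.03 and -0.04, differed in sign from the median.

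The next comparison asked whether the animals changed alike. MX1 rose in RhDBCb from 11.1 ± 6.53 CPM (SD over subsets, n = 4) to 58.9 ± 14.3 (n = 3) but went from 65.8 ± 18.4 to 48.1 ± 19.8 (n = 4 each) in RhM22, a difference of -2.89 on the log2 scale (SE 0.27, edgeR adjusted p = 0.000289). SREBF1 went from 19.9 ± 2.59 to 77.0 ± 14.9 CPM in RhDBCb and from 153 ± 26.4 to 112 ± 7.99 in RhM22 (difference -2.40, SE 0.25, adjusted p = 0.000648). The platelet chemokine PPBP differed by -2.53 (SE 0.37, 0.00381). JUN, a subunit of the AP-1 transcription factor, went from 658 ± 373 to 143 ± 20.2 CPM in RhDBCb and from 106 ± 18.0 to 126 ± 25.0 in RhM22 (difference 2.40, SE 0.37, 0.00517). Its partner FOS differed by 1.77 and TIPARP, an ADP-ribosyltransferase, by 2.37 (SE 0.37). In all, 679 of 14814 genes changed differently, 268 with a higher change in RhM22 and 411 with a lower one.

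Of 47 type I interferon-stimulated genes 8 were called in this comparison, all with a lower change in RhM22, and 15 adjusted over the list alone. Their median was -0.66 (camera adjusted p = 3.7e-08; adjusted p = 0.13 with an estimated correlation). Of 31 immediate early genes 7 changed more upward in RhM22 and 1 more downward, and 12 and 2 adjusted over the list alone (median 0.47, camera adjusted p = 0.00211; adjusted p = 0.835 with an estimated correlation). Platelet markers had a median of -2.40, with 2 of 11 members called and 4 adjusted over the list alone (camera adjusted p = 0.000307; adjusted p = 0.266 with an estimated correlation). Across genes, which are not independent replicates, the changes of the animals correlated at r = -0.06 (Spearman's rho -0.07). No gene was called in both animals in the same direction, and 3 were called in opposite directions. Each animal gave 1 draw per time, so the term compares 4 draws, and chance among draws is not excluded.

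The count of 679 depended on single libraries. It was 99 without the CD8 naive before library of RhM22, 116 without the CD4 naive after library of RhDBCb, 330 and 335 without the CD4 memory before and CD8 naive after libraries of RhM22, and 352 and 446 without its CD4 naive and CD4 memory after libraries. It was 389 and 441 without the CD4 naive before libraries of RhDBCb and RhM22, 446 without the CD8 memory after library of RhDBCb, 1021 without its CD4 memory after library and 1320 without its CD8 memory before library. Of the 22 called genes followed here 11, among them MX1, SREBF1, PPBP, JUN, FOS and TIPARP, kept their call in every such fit.

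**Figure D2:**
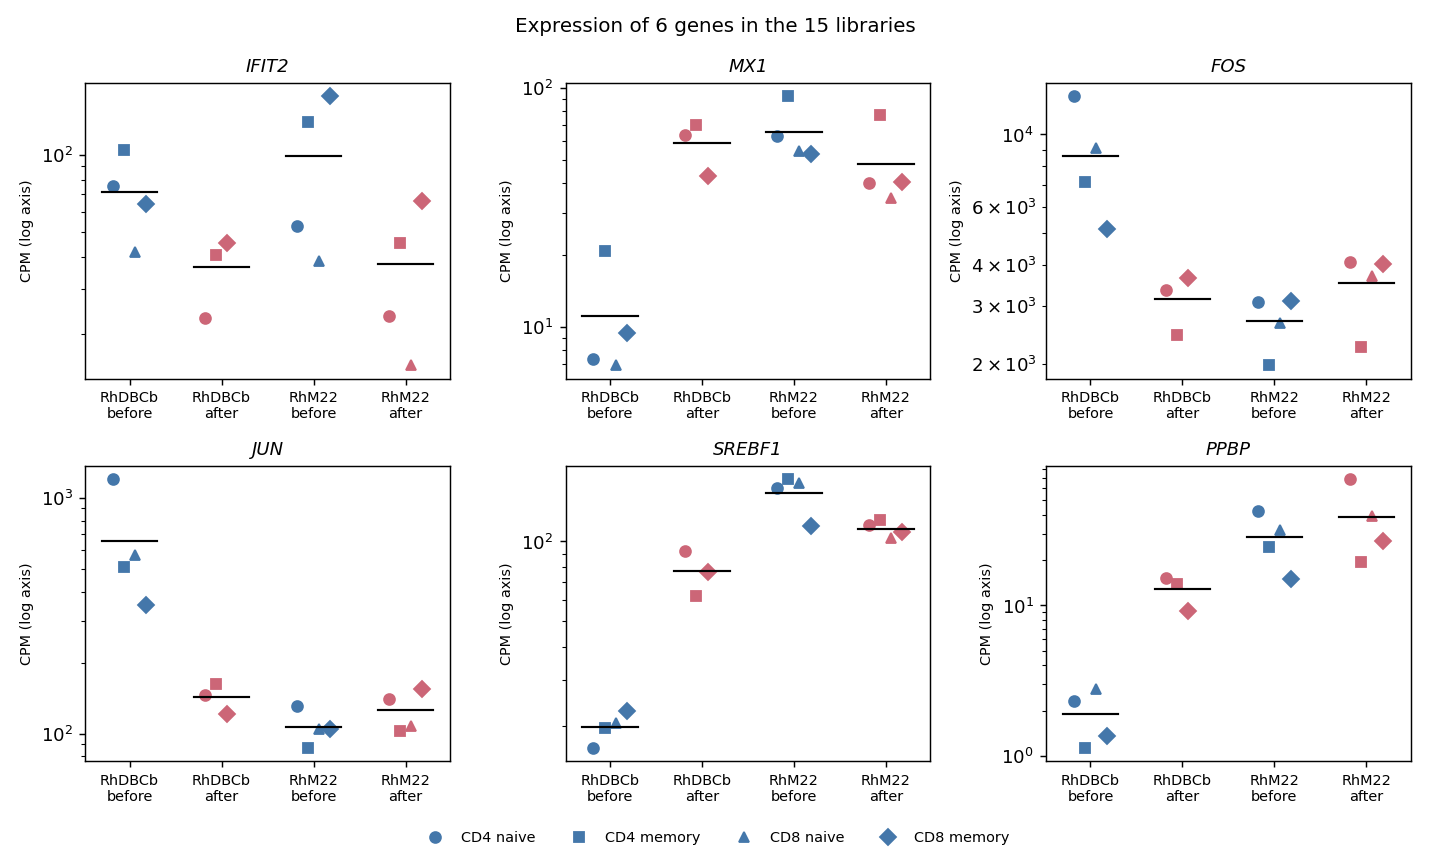
CPM (log axis) of IFIT2, MX1, FOS, JUN, SREBF1 and PPBP in each of the 15 libraries by animal and time, with the mean as a line and the marker shape giving the subset. MX1 in RhDBCb had a mean of 11.1 CPM before and 58.9 after treatment, and in RhM22 65.8 and 48.1.

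The animals were then followed singly, a comparison added after the data were seen. Each animal gave 1 draw per time, so p here measures spread among libraries and not among draws. In RhDBCb MX1 rose by 2.40 (log2; SE 0.20, adjusted p = 8.45e-05), MX2, its relative, by 1.81 (SE 0.47, 0.0288) and IRF7, the regulator of interferon genes, by 1.46 (SE 0.32, 0.0126), while IFIT2 fell by 1.36 (SE 0.27, 0.00913). CISH, a feedback inhibitor of cytokine signalling, rose by 2.94 (SE 0.35, 0.000687) and SREBF1 by 1.95 (SE 0.18, 0.000136). FNDC4 rose by 2.94 (SE 0.25, 8.45e-05). Among early response genes JUN fell by 2.14 (SE 0.29, 0.00136), DUSP1, a phosphatase that ends MAP kinase signals, by 1.94 (SE 0.32, 0.00395), and FOS by 1.41 (SE 0.22, 0.00342). CCNL1, a splicing cyclin, fell by 1.93 (SE 0.19, 0.000147), TSC22D3, a glucocorticoid-induced gene, by 1.44 (SE 0.19, 0.00127), and RGS1, a regulator of chemokine receptor signals, by 1.59 (SE 0.24, 0.00264). In sterol metabolism MSMO1 and IDI1 of cholesterol synthesis fell by 0.69 (SE 0.20, 0.0416) and 0.56 (SE 0.17, 0.0456), and LPIN1, of glycerolipid synthesis, rose by 0.76 (SE 0.18, 0.0198). Of the 28 targets of cholesterol synthesis and uptake 2 rose and 2 fell, 4 and 4 adjusted over the list alone (median -0.27, camera adjusted p = 0.761).

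Of 47 type I interferon-stimulated genes 9 rose and 2 fell in RhDBCb, 12 and 2 adjusted over the list alone (median 0.36, camera adjusted p = 0.0039; adjusted p = 0.869 with an estimated correlation). Of 31 immediate early genes 2 rose and 9 fell, 5 and 11 adjusted over the list alone (median -0.27, camera adjusted p = 0.00539; adjusted p = 0.997 with an estimated correlation). Their pair medians were -0.94 in CD4 naive, -0.325 in CD4 memory and 0.066 in CD8 memory cells. This list was drawn up for the immediate early and dissociation response, and the labels do not state how the subsets were separated. Platelet markers lay above 0 in 11 of 11 members (median 2.77, camera adjusted p = 1.34e-05; adjusted p = 0.232 with an estimated correlation), with 4 called and 6 adjusted over the list alone. Among them PPBP rose from 1.91 ± 0.794 (n = 4) to 12.8 ± 3.20 CPM (n = 3), and PF4, another platelet chemokine, rose by 2.80 (SE 0.57, adjusted p = 0.00967). The median log2 CPM of the platelet list in RhDBCb was -4.858 to -2.493 before and -0.712 to 0.562 after treatment. Its fold change was thus taken from a level near the floor, and its size is uncertain. Markers of monocytes and dendritic cells had a median of 0.72 (camera adjusted p = 0.27). Proliferation genes lay at -0.41 (0.0039; adjusted p = 0.997 with an estimated correlation) and oxidative phosphorylation at -0.25 (0.00525; adjusted p = 0.997 with an estimated correlation). Both rested on the CD8 memory pair, where the pair medians were -1.76 and -0.73, against 0.64 and -0.02 in the CD4 naive pair and -0.02 and 0.03 in the CD4 memory pair.

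In total 1499 genes were called in RhDBCb, 814 higher and 685 lower. Fitted on the 7 libraries of RhDBCb alone, 10 genes were called, 9 of them also among the 1499. That fit kept MX1, SREBF1, PPBP, CISH, FNDC4 and CCNL1 and lost JUN (adjusted p = 0.0565), FOS (0.0929), DUSP1 (0.11), IRF7 (0.158), MX2 (0.117) and IFIT2 (0.11). The count was 735 and 887 without its CD4 naive and CD4 memory before libraries, and 224 and 786 without its CD4 naive and CD8 memory after libraries. Without its CD4 naive after library the calls of IFIT2 (0.0616), MX2 (0.142) and IRF7 (0.0761) were lost. Without its CD4 naive before library those of MX2 (0.0919) and IRF7 (0.0525) were lost, and MX2 was also lost without its CD4 memory before (0.0896), CD4 memory after (0.0577) or CD8 memory after (0.0502) library. The call of LPIN1 was lost without its CD4 naive before (0.0589), CD4 memory before (0.0555), CD4 naive after (0.144) or CD8 memory after (0.0902) library. The calls of MSMO1 and IDI1 were the least steady, kept in 4 and 2 of 15 fits that left out 1 library. MSMO1 held without the CD8 memory before library of RhDBCb or RhM22, the CD4 naive before or the CD8 memory after library of RhM22, with adjusted p up to 0.187 otherwise. IDI1 held without the CD8 memory before library of RhDBCb or the CD8 memory after library of RhM22, with adjusted p up to 0.159 otherwise.

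In RhM22, 9 genes were called and all were lower after treatment. GBP3, an interferon-induced guanylate-binding protein, fell by 1.56 (log2; SE 0.20, adjusted p = 0.02), IFIT3 by 1.37 (SE 0.22, 0.0387) and PSMB8, a subunit of the immunoproteasome, by 0.80 (SE 0.12, 0.0387). STAT3, the transcription factor of IL-6 family signals, fell by 0.90 (SE 0.13, 0.0269), TRAF1, an adaptor of TNF receptors, by 0.79 (SE 0.13), and GNL3, a nucleolar GTPase, by 0.79 (SE 0.11, 0.0269). TMEM140 fell by 1.61 (SE 0.25, 0.0387) and ARID4B, a chromatin gene, by 0.84 (SE 0.13). PSMB8 went from 1229 ± 99.0 to 713 ± 109 CPM (n = 4 each). Type I interferon-stimulated genes lay above 0 in 10 of 47 members (median -0.26, camera adjusted p = 3.55e-11), with 2 called and 8 adjusted over the list alone. Interferon-gamma and antigen presentation genes lay above 0 in 4 of 19 (median -0.20, 6.7e-08). Both lists held with an estimated correlation, each at adjusted p = 0.0308. These p values measure spread among libraries, and RhM22 gave 1 draw per time, so chance among draws is not excluded.

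NF-kB genes in RhM22 had a median of -0.28 (camera adjusted p = 7.35e-07; adjusted p = 0.117 with an estimated correlation). Glycolysis lay at -0.16 (0.00601; adjusted p = 0.439 with an estimated correlation) and the unfolded protein response at -0.10 (0.0238; adjusted p = 0.117 with an estimated correlation). The 28 targets of cholesterol synthesis and uptake had a median of 0.04 with 0 called (0.56), and their difference between the animals was 0.34 (0.511). B cell markers lay at 1.36 (0.0112; adjusted p = 0.117 with an estimated correlation), and platelet markers at 0.53 (0.0496; adjusted p = 0.389 with an estimated correlation). The B cell pair medians in RhM22 were 0.073 and 1.141 in CD4 naive and memory and 0.745 and 1.182 in CD8 naive and memory cells. Each lay below the fitted value, and the median log2 CPM of the list was at most -1.101 in this animal's libraries. Fitted on the 8 libraries of RhM22 alone, 61 genes were called, 9 of them shared. The count of 9 was 0 without any 1 of the 4 before libraries, the CD4 naive after or the CD8 naive after library of RhM22, and 2 without its CD4 memory after library. It was 4, 3 and 5 without the CD4 memory before, CD4 naive after or CD4 memory after library of RhDBCb, and 15 without its CD8 memory before library. GBP3 kept its call in 9 of 15 such fits, STAT3 in 8, GNL3 in 7, PSMB8 in 6, TMEM140, IFIT3 and ARID4B in 3, and TRAF1 in 2.

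**Figure D3:**
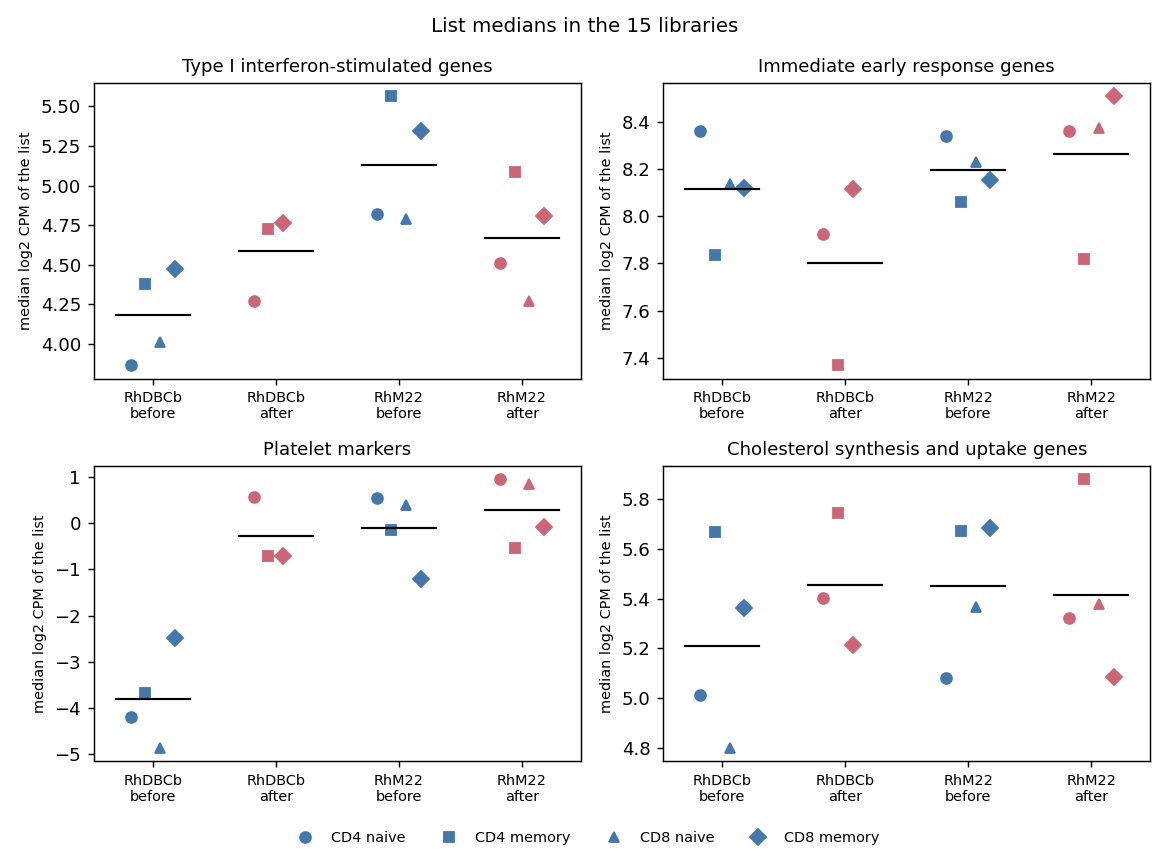
Median log2 CPM of type I interferon-stimulated genes, immediate early genes, platelet markers and targets of cholesterol synthesis and uptake in each of the 15 libraries by animal and time, with the mean as a line. The median change of the interferon-stimulated genes was 0.36 in RhDBCb and -0.26 in RhM22.

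Within single subsets no gene passed the test. In CD4 naive cells BCL6 lay at -1.53 (SE 0.35, adjusted p = 0.897) and INPPL1, a phosphoinositide phosphatase, at 2.64 (SE 0.55, 0.897), while BICDL2 had 85 and 10 counts before and 0 and 0 after treatment. In CD4 memory cells IFIT2 lay at -1.46 (SE 0.37, adjusted p = 1) and NABP1 at -1.23 (SE 0.31, 1), and PEAK1, a pseudokinase, had 89 and 17 counts before and 0 and 0 after. In CD8 naive cells SYNE2, of the nuclear envelope, lay at -2.21 (SE 0.53, adjusted p = 1). In CD8 memory cells SPECC1L lay at 0.96 (SE 0.24, adjusted p = 1) and WDR13 at -0.81 (SE 0.22, 1). At an unadjusted p under 0.05 edgeR held 603 genes in CD4 naive, 230 in CD4 memory, 148 in CD8 naive and 216 in CD8 memory cells. DESeq2 called 9 in CD4 naive and 0 in each of the others. CD8 naive cells after treatment are 1 library, assumed to vary like the other groups.

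Within subsets camera called 22 lists, with 0 members called in any and none of the 22 held with an estimated correlation. In CD8 memory cells proliferation genes had a median of -0.87 with 4 of 45 above 0 (camera adjusted p = 1.54e-13; adjusted p = 0.424 with an estimated correlation). Their pair median was -1.76 in RhDBCb and 0.39 in RhM22. MKI67 lay there at -1.23 (SE 0.93), with -3.35 in RhDBCb and 0.76 in RhM22. Cytotoxic genes had a median of 0.47 with 22 of 26 above 0 (2.51e-07; adjusted p = 0.424 with an estimated correlation), such as GZMB at 0.72 (SE 0.42) and CX3CR1, a receptor of effector cells, at 1.79 (SE 1.29). In the same cells platelet markers lay at 1.75 (0.00019), B cell markers at 0.78 (0.0388), natural killer markers at 0.28 (0.0174), CD4 lineage markers at -0.43 (0.0117), oxidative phosphorylation at -0.21 (2.51e-07), glycolysis at -0.30 (0.000652) and interferon-gamma genes at -0.21 (0.0117). The pair median of oxidative phosphorylation was -0.73 in RhDBCb and 0.22 in RhM22. With an estimated correlation the adjusted p of these lists was 0.424, 0.482, 0.557, 0.424, 0.633, 0.424 and 0.424 in that order.

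In CD8 naive cells, before and after in RhM22 and before in RhDBCb, cytotoxic genes had a median of -0.77 with 1 of 26 above 0 (camera adjusted p = 2.99e-09; adjusted p = 0.406 with an estimated correlation). Memory markers lay at -0.46 (1.24e-05; adjusted p = 0.406), NF-kB genes at -0.49 (0.00248; adjusted p = 0.406), interferon-gamma genes at -0.24 (0.00436; adjusted p = 0.406), type I interferon-stimulated genes at -0.32 (0.000151; adjusted p = 0.5), natural killer markers at -0.67 (0.0383; adjusted p = 0.5) and platelet markers at 0.89 (0.0383; adjusted p = 0.575), the second p of each with an estimated correlation. These fitted values also draw on the before library of RhDBCb, which has no after library here to pair with. In the pair of RhM22 the medians were -0.411 for cytotoxic genes, -0.376 for memory markers and -0.363 for NF-kB genes. They were -0.228 for interferon-gamma genes, -0.374 for type I interferon-stimulated genes, -0.477 for natural killer markers and 0.213 for platelet markers. In CD4 naive cells mitochondrially encoded genes lay at 0.64 (4.43e-08), platelet markers at 1.76 (0.000357), ribosomal proteins at 0.14 (0.00499), NF-kB genes at -0.31 (0.0148), immediate early genes at -0.22 (0.0149) and interferon-gamma genes at -0.42 (0.00499). The CD4 naive pair medians of RhDBCb and RhM22 were -0.94 and 0.14 for immediate early genes, -0.08 and 0.40 for ribosomal proteins and 0.16 and 1.25 for mitochondrially encoded genes. For platelet markers they were 5.56 and 0.56, the value of RhDBCb taken from a level near the floor. The adjusted p with an estimated correlation was 0.752 for interferon-gamma genes and 0.972 for the other 5. In CD4 memory cells no list was called. Without the CD8 memory after library of RhM22 camera called 14 lists in place of 22.

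Whether memory and naive cells, or CD8 and CD4 cells, changed differently was tested directly, and no gene passed either test. For memory against naive cells GZMB, a granzyme, lay at 1.81 (SE 0.46) and CSF1, a macrophage growth factor, at 1.67 (SE 0.38). For CD8 against CD4 cells RAP1GAP2 lay at -1.38 (SE 0.36). The adjusted p was 1 for each. At an unadjusted p under 0.05 edgeR held 214 genes in the first test and 147 in the second, and DESeq2 called 0 and 1. Cytotoxic genes had a median difference of 0.88 between memory and naive cells (camera adjusted p = 2.2e-06; adjusted p = 0.745 with an estimated correlation). Proliferation genes had one of -0.47 (0.00173), mitochondrially encoded genes -0.39 (0.00103) and ribosomal proteins -0.12 (0.0247), with an adjusted p of 0.745, 0.745 and 0.809 with an estimated correlation. Between CD8 and CD4 cells immediate early genes had a median difference of 0.25 (0.00164), proliferation genes -0.37 (0.000218), mitochondrially encoded genes -0.39 (3.81e-06), memory markers -0.36 (8.01e-05) and type I interferon-stimulated genes -0.21 (0.0158), each at adjusted p = 0.735 with an estimated correlation. Oxidative phosphorylation lay at -0.11 (0.019) and ribosomal proteins at -0.10 (0.00397), at adjusted p = 0.885 and 0.844 with an estimated correlation. CD8 naive cells after treatment came from RhM22 alone, so both tests are in part mixed with the difference between the animals. Immediate early pair medians in RhM22 were 0.014 and 0.217 in CD8 naive and memory, and 0.142 and 0.115 in CD4 naive and memory cells. In RhDBCb they were -0.94 and -0.325 in CD4 naive and memory and 0.066 in CD8 memory cells.

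Before treatment, memory and naive CD4 cells were compared to describe the subsets. TMIGD2, a co-stimulatory receptor, was lower in memory cells by a log2 fold change of -3.80 (SE 0.41, adjusted p = 0.00448), as were RIN3, a Rab5 activator, at -2.95 (SE 0.34, 0.00631) and SMAD1, of BMP signalling, at -5.14 (SE 0.96, 0.0253). CGA, the shared alpha chain of the glycoprotein hormones, was higher at 6.18 (SE 0.86, 0.00767) and CHDH, choline dehydrogenase, at 6.25 (SE 0.87, 0.00767). KIAA1217 had 62 and 45 counts in memory and 0 and 0 in naive libraries. Among list members, GZMK, a granzyme, was higher at 4.74 (SE 0.46), CCR6, a chemokine receptor of Th17 cells, at 3.68 (SE 0.47) and S100A4, a calcium-binding protein, at 4.06 (SE 0.59). Of 23 T helper genes 10 were higher, 15 adjusted over the list alone (camera adjusted p = 1.52e-19; adjusted p = 0.00846 with an estimated correlation). Of 23 memory markers 10 were higher, 19 adjusted over the list alone (2.35e-22; adjusted p = 0.0267). Of 22 naive genes 0 were called, and 11 were lower adjusted over the list alone (median -0.85, 7.56e-09; adjusted p = 0.0285).

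In this CD4 contrast 165 genes were called, 137 higher and 28 lower in memory cells. The count was 3 without the CD4 naive before library of RhDBCb, where CGA (adjusted p = 0.128), CHDH (0.128), RIN3 (0.0592), SMAD1 (0.195), GZMK (0.064), CCR6 (0.0805) and S100A4 (0.143) were lost, and 66 and 29 without the CD4 memory before libraries of RhDBCb and RhM22, which ended the call of SMAD1 (0.167 and 0.195) and, for RhM22, of CHDH (0.0514) and S100A4 (0.0545). Without the animal block 2 genes were called.

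The same contrast in CD8 cells gave 484 genes, 341 higher and 143 lower in memory cells. ADAM19, a membrane protease, was higher at 5.44 (log2; SE 0.70, adjusted p = 0.00345) and CCR4, a chemokine receptor of tissue-homing cells, at 4.69 (SE 0.66, 0.00534). RASGRF2, a Ras activator, was lower at -4.61 (SE 0.60, 0.00361), FHL1 at -4.80 (SE 0.75), and LEF1 and BACH2, transcription factors of naive cells, at -2.35 and -2.59. Of 22 naive genes 8 were lower, 12 adjusted over the list alone (median -0.86, camera adjusted p = 1.38e-09; adjusted p = 0.021 with an estimated correlation). Of 23 memory markers 15 were higher, 19 adjusted over the list alone (3.01e-19; adjusted p = 0.021). Of 45 proliferation genes 16 were higher, 33 adjusted over the list alone (median 2.54, 5.21e-18; adjusted p = 0.155). The count of 484 was 133 and 255 without the CD8 naive before libraries of RhDBCb and RhM22, 80 without the CD8 memory before library of RhDBCb, and 15 without the animal block. LEF1 was lost without the CD8 naive (adjusted p = 0.126) or CD8 memory (0.196) before library of RhDBCb. BACH2 was lost without these (0.089 and 0.305) or without the CD8 naive (0.109) or CD8 memory (0.0856) before library of RhM22.

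CD8 and CD4 cells before treatment were compared in the same way. In naive cells CD8B was higher in CD8 cells at 9.42 (log2; SE 0.42, adjusted p = 8.53e-07), CD8A at 8.82 (SE 0.52, 1.04e-05) and CD4 lower at -8.26 (SE 0.63, 5.12e-05). CTSW, a protease of cytotoxic cells, was higher at 7.03 (SE 0.45), the chemokine CCL5 at 6.37 (SE 0.82) and GZMK at 5.26 (SE 0.47), while CXCR5, the follicular homing receptor, was lower at -3.34 (SE 0.25). Of 26 cytotoxic genes 12 were higher, 23 adjusted over the list alone (median 3.90, camera adjusted p = 5.73e-36; adjusted p = 0.039 with an estimated correlation). In memory cells CD8B and CD8A were higher at 8.76 (SE 0.41, 1.5e-06) and 8.35 (SE 0.51, 1.31e-05), CD4 lower at -8.14 (SE 0.63, 7.93e-05), and PRF1, perforin, higher at 4.67. There 13 of 26 cytotoxic genes were higher, 23 adjusted over the list alone (median 2.88, 4.87e-36; adjusted p = 0.0555 with an estimated correlation). KLRF1, NKG2D and TRGV9 were also higher at 8.02, 6.08 and 7.25, but belong to gene families whose reads can be shared, so their values are uncertain.

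The contrast of naive cells called 120 genes, 83 higher in CD8 cells, and that of memory cells 143, 95 higher. The first count was 31 and 37 without the CD4 naive and CD8 naive before libraries of RhDBCb, and 38 without the animal block. The second was 19 and 50 without the CD4 memory before libraries of RhDBCb and RhM22, 56 and 80 without their CD8 memory before libraries, and 29 without the animal block. CD8A, CD8B and CD4 kept their calls in each fit that left out 1 library. CCL5 in naive cells was lost without the CD4 naive before library of RhDBCb (adjusted p = 0.0731). PRF1 in memory cells was lost without the CD4 memory before library of RhDBCb (0.12) or RhM22 (0.117), and so was TRGV9 (0.146 and 0.058).

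The animals were also compared with each other at each time, again added after the data were seen. Here too each side is 1 draw, so p does not measure spread among draws. Before treatment 5577 genes differed, 2868 higher and 2709 lower in RhM22, and after treatment 954 did, 488 higher and 466 lower. The complement gene CFB was higher in RhM22 at both times, at 16.6 ± 8.55 against 0.00424 CPM before (SD over subsets, n = 4 each) and 11.8 ± 5.34 (n = 4) against 0.0574 (n = 3) after. The Y-linked genes UTY, ZFY and DDX3Y were high in RhDBCb alone, such as UTY at 61.2 ± 19.4 against 0.0603 ± 0.0217 CPM before treatment. By these genes the animals differ in sex, which cannot be told apart from other differences between them. COL14A1, a fibril-associated collagen, had 0 counts in all 8 libraries of RhM22 and a mean of 13.4 ± 8.64 CPM in RhDBCb before treatment. Type I interferon-stimulated genes were higher in RhM22 before treatment, with 29 of 47 members higher and 2 lower both over all genes and adjusted over the list alone (median 0.87, camera adjusted p = 2.55e-06; adjusted p = 0.169 with an estimated correlation). After treatment 1 was higher and 1 lower (median 0.21, 0.27).

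Platelet markers were higher in RhM22 before treatment in 7 of 11 members, 8 adjusted over the list alone (median 3.30, camera adjusted p = 0.00153; adjusted p = 0.383 with an estimated correlation), and in 2 after, 3 adjusted over the list alone (median 0.37, 0.103). The list lay near the floor in the before libraries of RhDBCb. The count of 954 after treatment was 214, 254 and 1572 without the CD4 naive, CD4 memory and CD8 memory after libraries of RhDBCb. It was 251, 281, 392 and 2082 without the CD4 naive, CD4 memory, CD8 naive and CD8 memory after libraries of RhM22, and 602 and 582 without its CD4 memory and CD8 naive before libraries. Fitted on the after libraries alone, 165 genes differed.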

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

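The tests on the animals' levels at each time, monocyte markers, platelet and other blood cell markers and the number of draws were chosen only after the result was seen, as were the comparisons within each animal. A test of the difference between the animals drew attention to 7 results. The number of genes whose change differed was 679, type I interferon-stimulated genes as a list differed by -0.655 (median), and platelet markers by -2.402. SREBF1 differed by -2.398, MX1 by -2.889, FOS by 1.769 and JUN by 2.396, each as RhM22 minus RhDBCb on the log2 scale. No subset-by-time group held more than 2 libraries, so no test for an outlying library was run within a group, and fits that left out each library in turn took its place.

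More genes were called in RhDBCb (1499) than in RhM22 (9) where all libraries shared 1 estimate of the spread. Fitted on each animal's own libraries the order turned, with 10 in RhDBCb and 61 in RhM22, so the order of the counts depends on the fit. RhDBCb has fewer libraries and pairs than RhM22, so the counts of the own fits are not of like power. The median absolute log2 change in the shared fit was 0.436 in RhDBCb and 0.212 in RhM22. With the immediate early genes taken out of the counts 1493 genes were still called in RhDBCb. TMM scaling already limits the weight of a few abundant genes, so that count could hardly fall. It does not decide whether an early response reached other genes. With all libraries thinned to the smallest total 1537 genes were called, which argues against unequal total counts as the whole cause. Thinning does not make the number of genes detected equal. The CD8 naive before library of RhDBCb had the highest total (71787211) but 13881 genes detected, so a difference in detection was not addressed. The number of genes that differed between the animals was 5.85 times as high before (4 against 4 libraries) as after treatment (3 against 4). A before draw of RhDBCb that stood apart whatever the treatment did would give such a ratio. So would a response that moved RhDBCb toward RhM22, so the ratio does not decide between them. That ratio ran from 2.75 without the CD8 memory after library of RhM22 to 25.2 without the CD4 naive after library of RhDBCb, and it was 22.4 and 3.58 without the CD4 memory and CD8 memory after libraries of RhDBCb and 21.2, 18.7 and 13.5 without the CD4 naive, CD4 memory and CD8 naive after libraries of RhM22. A response to treatment that RhM22 lacks stays open, because RhDBCb gave 1 before draw.

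Type I interferon-stimulated genes had a median change of 0.36 in RhDBCb and -0.26 in RhM22. In 7 pairs the summed CPM of monocyte and dendritic cell markers changed by at most 0.0447 times as much as that of the interferon-stimulated list, and in the same direction in 3, which argues against such cells carried along with the T cells. For the rise in RhDBCb a low level in its before draw stays open: the animals differed by a median of 0.87 before and 0.213 after treatment, but the fall in RhM22 narrowed that difference too. The number of untreated draws after the start is 0, so a response to treatment of opposite direction in the animals also stays open.

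Platelet markers were higher after treatment in RhDBCb in 100% of the measured members, which is the pattern itself and decides nothing, so platelets or their RNA carried along with the T cells are a candidate explanation that stays open. PPBP and PF4 are platelet genes, and PPBP reached a mean of 12.8 CPM. The median log2 CPM of the list in RhDBCb before treatment was -4.858 to -2.493, near the floor, so the size of its rise is uncertain. The lowest median among erythroid, neutrophil, monocyte and B cell markers was -0.577, for B cells, but their pair medians in RhDBCb were 0, 0 and 0.33 and their median level stayed below 1 CPM in each of its libraries, so a general carry-over of blood cells stays open. No biological explanation was tested, and a change in the animal's platelets stays open.

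Splits of the libraries into other groups of the same sizes asked whether chance can be excluded among libraries. For treatment over all subsets 3 of 50 splits called as many genes as the real one (1 gene), so chance cannot be excluded. The highest other split called 58 and joined the after libraries of RhDBCb with the before libraries of RhM22, which points to a structure of the samples: in a model with animal this split is the animal-by-time contrast. For the difference between the animals 1 of 50 splits, the real one, called 679, and the highest other called 307, so chance can be excluded among libraries. The 1 other split that kept draws whole called 200. Its term equals the change under treatment averaged over the animals, so 200 is not a count under chance. With 4 draws chance is not excluded among draws. In RhDBCb 1 of 35 splits gave as many (1499, highest other 1393), and in RhM22 1 of 35 (9, highest other 4). Few of these splits part all the pairs of a subset as the real one does. They are too few for a share under 5%, so chance is not excluded among comparable splits. The split with 1393 put the CD8 memory before library of RhDBCb with its after libraries, and among splits that part all 3 pairs, as the real one does, the highest other called 74. For the animals before treatment 1 of 35 splits gave as many (5577, highest other 0), with the same limit on comparable splits. After treatment 2 of 35 gave as many (954, highest other 1803), so chance cannot be excluded, and the split with 1803 moved the CD8 memory after library of RhM22 to the side of RhDBCb. Libraries of 1 draw share its animal and day, and nearly all splits break the draws up, so none of these counts excludes chance among the draws.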

How the results depend on the processing

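Tests of the change within each animal, of the animals at each time and of the fit without the before libraries of RhDBCb were chosen only after the data were seen. For treatment over all subsets (1 gene) the count was 0 without the animal block, 177 with DESeq2 (94 higher, 83 lower), 0 with voom and the draw as a random block, 4 with the stricter filter, 0 with log2(FPKM + 1), 0 with log2(FPKM + 0.1) and 2 with unfiltered FPKM. It was 10 in RhDBCb alone, 61 in RhM22 alone, 0 without the CD8 naive libraries, 0 as the mean of the 4 subset contrasts and 11 without the before libraries of RhDBCb, a fit that gives the change in RhM22. With the animal-by-time term in the model the count for the change averaged over the animals was 200. In single subsets (0 genes by edgeR) DESeq2 called 9 in CD4 naive cells. Unfiltered FPKM called 6 in CD4 naive, 5 in CD4 memory, 143 in CD8 naive and 9 in CD8 memory cells. Filtered log2(FPKM + 1) called 2 in CD4 memory and 8 in CD8 naive cells, and log2(FPKM + 0.1) called 4 in CD8 naive cells. For memory against naive effects (0) the FPKM counts were 3, 3 and 109, and for CD8 against CD4 effects (0) 2, 2 and 106, with log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered values, while DESeq2 called 1 in the latter. The FPKM fits warned of genes with no variance.

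For the difference between the animals (679) the count was 440 at 2-fold, 1671 with DESeq2 and 426 with unfiltered FPKM. For CD4 memory against naive (165) it was 2 without the block, 694 with DESeq2, 36, 97 and 14 with the 3 FPKM settings, 31 without the before libraries of RhDBCb and 818 with only the groups compared. For CD8 memory against naive (484) it was 15 without the block, 1433 with DESeq2, 872 with voom, 302 with log2(FPKM + 1), 152 unfiltered and 52 without the before libraries of RhDBCb. For CD8 against CD4 naive (120) it was 38, 387 and 79 without the block, with DESeq2 and with voom, 29, 58 and 30 with FPKM, 31 without the before libraries of RhDBCb and 220 with only the groups compared. For CD8 against CD4 memory (143) it was 29 without the block, 491 with DESeq2, 93 and 59 with log2(FPKM + 1) filtered and unfiltered, 48 without the before libraries of RhDBCb and 349 with only the groups compared. In RhDBCb (1499) it was 526 at 2-fold, 2519 with DESeq2, 930 with unfiltered FPKM and 10 on its own libraries. In RhM22 (9) it was 4, 248 with DESeq2, 1 with log2(FPKM + 0.1) and 61 on its own libraries. The animals differed at 2-fold in 2657 genes before (5577), and after (954) in 468 at 2-fold, 2202 with DESeq2, 533 with unfiltered FPKM and 165 on the after libraries alone. Of 6 lists over all subsets and 22 per subset, 0 and 0 held with an estimated correlation, and fry called 0 and 0.

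Leaving out 1 library gave 0 to 3 for treatment over all subsets, 0 in each subset and for the differences between subsets, 99 to 1320 between the animals, 3 to 190 for CD4 and 80 to 542 for CD8 memory against naive, 31 to 170 for CD8 against CD4 naive and 19 to 154 for memory. It gave 224 to 2178 in RhDBCb, 0 to 15 in RhM22, 4321 to 5729 for the animals before and 214 to 2082 after, 4 to 8 lists over all subsets and 14 to 25 per subset.

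Among genes over all subsets these changed sign. In RhM22 alone and without the before libraries of RhDBCb, SQLE was 0.093 and 0.079, INSIG1 0.08 and 0.073, ABCA1 -0.431 and -0.407, SREBF1 -0.429 and -0.441, MYLIP 0.049 and 0.068, MX1 -0.484 and -0.483, MKI67 0.621 and 0.535, CD69 0.004 and 0.033, PRF1 -0.102 and -0.122, FOS 0.367 and 0.363, JUN 0.245 and 0.244, TOP2A -0.071 and -0.048, and CD4 0.051 and 0.008. CD8B was 0.043 in RhM22 alone. In RhDBCb alone HMGCS1 was -0.566 and IL2RA 0.189. Without the CD8 naive libraries HMGCS1 was -0.103. With log2(FPKM + 1), filtered or not, ABCA1 was -0.001, TOP2A -0.017, CD4 0.156 and the animals' difference of PF4 0.045. With voom TOP2A was -0.07, CD4 0.358 and CD8A -0.066. CD4 was 0.008 without the block, 0.008 without a filter, 0.01 with the stricter filter and 0.122 with log2(FPKM + 0.1). Leaving out 1 library gave HMGCS1 -0.11 to 0.207, ABCA1 -0.089 to 0.37, PRF1 -0.11 to 0.33, TOP2A -0.213 to 0.346, CD4 -0.116 to 0.202 and CD8A -0.078 to 0.174. In CD8 memory cells MKI67 ran from -2.782 to 0.108 and MCM2 from -2.49 to 0.277, and both were above 0 (0.391 and 0.132) without the before libraries of RhDBCb.

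Of the values of 237 genes in a comparison under the other settings, 1979 kept sign and side of the threshold, 282 lost and 23 gained a call and 47 changed sign. With 1 library left out the numbers were 3199, 309, 8 and 25. Only the groups compared could not be fitted for CD8 naive cells. The CD8 naive after library of RhM22 could not be left out of comparisons that need it. The random block by draw was not run for the difference between the animals or the added comparisons, where it equals the term tested.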

Other observations

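The levels of markers for other cells and the signs of change in each animal were looked at only after the data were seen. In RhM22 B cell markers had a fitted median change of 1.36, against -0.58 in RhDBCb, where the pair medians were 0, 0 and 0.33, and the difference between the animals was 1.10 (camera adjusted p = 0.364). The pair medians in RhM22 ran from 0.073 to 1.182. Its libraries held a median log2 CPM of -2.206 to -1.101 for the list, so both changes rest on low levels. Across genes, which are not independent replicates, 41.2% of the genes called in RhDBCb had the same sign in RhM22, and the median absolute log2 change was 0.436 in RhDBCb and 0.212 in RhM22. Proliferation genes were lower in RhM22 than in RhDBCb before treatment, with 14 of 45 members lower and 1 higher (median -1.10, camera adjusted p = 0.000124; adjusted p = 0.574 with an estimated correlation). MKI67 had a mean of 35.4 ± 51.6 CPM (SD over subsets, n = 4) in RhDBCb before and 9.77 ± 6.45 (n = 3) after treatment, and 3.68 ± 4.03 and 4.94 ± 5.10 (n = 4 each) in RhM22. The before mean of RhDBCb rests on its CD8 memory library at 112 CPM, while its CD4 naive, CD4 memory and CD8 naive libraries held 3.36, 19.9 and 6.19 CPM of MKI67. Markers of monocytes and dendritic cells were higher in RhM22 before treatment (median 1.98, 0.0117; adjusted p = 0.574 with an estimated correlation), with 6 of 20 members called.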
